A study of Rhagoletis zephyria and Rhagoletis pomonella with 20 samples.

How the data were processed

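Per the labels, the parents came from infested fruit kept at 21 °C with 14 h of light and 10 h of dark, and their pupae were held at 21 °C for 10 days and then at 4 °C for 20 weeks. The adults were crossed in cages, their eggs were moved into apple or snowberry fruit, and whole feeding larvae of the third instar were frozen for RNA. From each larva 250 ng of RNA was labelled with Cy3 (larvae 1 to 3 of a group) or Cy5 (larvae 4 to 6), so dye and larva number went together. The 17 larvae (6 PA, 5 ZA, 6 ZS) filled 12, 14 and 14 channels of 20 custom 2-colour arrays with 60-base probes, 4 arrays on each of 5 slides, with no common reference. The design had 18 different pairs of larvae, and 2 arrays repeated a pair.

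The deposited array files hold the mean pixel intensity of each spot and the median intensity of its local background, as scanned, and processed intensities that Agilent Feature Extraction 10.1.1.1 had background-subtracted, detrended and dye-normalized, per the file headers. The authors also deposited a table of log2 differences between group means made with limma, whose version, background correction and normalization are not stated in it. Its 3 columns are PA minus ZA, PA minus ZS and ZS minus ZA, so the first 2 have the opposite sign to the differences used here. The FlyBase hit of each target came from that table, as did the gene symbols and names.

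Each array held 45220 spots, of which 1417 were controls. Control spots and spots marked as outliers by Feature Extraction were left out, and spots of the same probe were averaged. Median raw signals per array were 62.0 to 129 in Cy3 (background 44 to 49) and 95.8 to 162 in Cy5 (background 73 to 81), and at most 0.00229% of spots in a channel were saturated. A probe was kept if it was well above background in at least 50% of the channels of at least 1 group, which held for 28978 of 43623 probes. The value of a target was the mean of its kept probes. This left 16561 of 23004 targets, of which 11512 had a FlyBase hit (6077 genes) and 5734 a gene name. By dye, 63.3% of probes were well above background in Cy3 and 59.2% in Cy5. The number of arrays limits the precision, and no other measure of depth applies.

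Mean signals were background-corrected by normexp with an offset of 50 and normalized by loess within arrays in limma 3.58.1 (R 4.3.3, data.table version 1.17.8, jsonlite 2.0.0). The repeated pairs were averaged, and their arrays correlated at 0.887 and 0.947 across targets, which are not independent replicates. Because larvae were shared between arrays, the 18 log ratios were transformed by generalized least squares with 1 share of variance between larvae for all targets, estimated at 0.7. The limma linear model had the group of each channel and a dye term, with 15 residual and 2.18 prior degrees of freedom. The contrasts were ZA minus PA, ZS minus ZA and ZS minus PA. A target was called, or passed, at a Benjamini-Hochberg adjusted p under 0.05 over all targets. Errors of differences are standard errors of the limma model, and those of group means are standard deviations between larvae of the log2 signal per larva, so a fitted difference can differ from that of the means.

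The model was tested on simulated data with the same design. With no change in any group it called 0 targets in each contrast, and 5.09%, 5.01% and 5.16% of targets had an unadjusted p under 0.05 for ZA minus PA, ZS minus ZA and ZS minus PA. Ordinary limma, which treats arrays that share a larva as independent, called 58, 199 and 11 in the same data. A log2 change of 1 was called in 80%, 82% and 80% of 50 changed targets, and one of 0.5 in 40%, 46% and 48%. The simulated targets varied independently of each other, with the share of variance between larvae that the model assumes. In real larvae many targets can depart together, which the simulation left out, so its error rates need not hold for them.

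The targets named in the text followed a rule. In each contrast these were the 12 highest and 12 lowest called targets with a gene name that were well above background in at least 50% of the channels of both groups, and the 3 members of each gene list with the smallest p. For targets below background in every channel of a group, the 3 largest bounds in each direction were taken, with the dim group set at its background level. Of 28 gene lists matched by symbol or name, 26 were tested: cytochrome P450s, glutathione S-transferases, UDP-glycosyltransferases, carboxylesterases, ABC transporters, digestive proteases, carbohydrate digestion, lipases and fat metabolism, peritrophic matrix and chitin, larval storage proteins, cuticle proteins, ecdysone and juvenile hormone response, antimicrobial peptides and immune recognition, haemocyte markers, heat shock proteins, antioxidant genes, chemosensory genes, ribosomal proteins, mitochondrial respiration, DNA replication and cell cycle, muscle, testis-biased genes, ovary, yolk and chorion, neuropeptides and insulin signalling, amino acid and nitrogen metabolism, and sugar and polyol metabolism. The salivary gland list matched 1 target and the list of transposable elements 0. Symbols that matched by accident, such as mitochondrial ribosomal proteins among the ABC transporters, stayed in the lists, and an alternative left them out.

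Each list was tested with limma's camera at a preset correlation of 0.01 between members, adjusted over 78 tests (26 lists and 3 contrasts). Members were targets, so several targets of the same Drosophila gene counted separately. Camera compares a list with all other targets. It was repeated with an estimated correlation, with which 0 of the 20 calls held, and with fry, which tests whether the members of a list move on balance one way and compares them with no other targets. The share of probes well above background was compared between groups by a two-sided exact permutation test over larvae within dyes. For the relation of the species difference to the fruit response, groups without effects were simulated 100 times and the ZA larvae were split into separate sets.

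The contrasts, filters, lists, naming rule and the alternatives except 4 were fixed before the data were examined. Of those 4, 3 left out targets with 1 probe on each strand, accidental list members, and larva ZA-2 as a doubted sample, although leaving out each larva in turn was planned. The last repeated camera with an estimated correlation without the accidental members and without ZA-2. The alternatives covered background correction, normalization, the filter on dim probes, the treatment of shared larvae, dye, slide, repeated arrays, probes of the same target, thresholds, the list test and larvae left out in turn. Testing the deposited differences was left out, since they have no values per sample. Their columns correlated with the fitted differences at 0.907, 0.918 and 0.892 across targets and were larger, with slopes of 1.45, 1.43 and 1.38, and 100% of called targets had the same sign once directions were aligned. Against differences from processed signals the correlations were 0.983, 0.988 and 0.963.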

Results

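Gene expression was measured in whole feeding larvae of the third instar from 2 fruit flies, the apple maggot Rhagoletis pomonella and the snowberry maggot Rhagoletis zephyria. Per the labels, eggs from laboratory crosses were moved into fruit, and the larvae were frozen individually. The 17 larvae formed 3 groups: 6 R. pomonella in apple (PA), 5 R. zephyria in apple (ZA) and 6 R. zephyria in snowberry (ZS). Per the series description, R. pomonella did not survive in snowberry, so no array held that combination. Each of 20 arrays on 5 slides compared 2 larvae, one in the red dye Cy5 and one in the green dye Cy3. There were 6 arrays of ZA against PA, 6 of ZS against PA and 8 of ZA against ZS, and every larva was on 2 to 4 arrays. The probes represented 23004 assembled sequences (called targets here) of R. pomonella transcripts, of which 16561 were bright enough to test. Targets carry the symbol of the Drosophila gene that the authors matched to them, so several targets can share a symbol and related genes can be hard to tell apart. Genome positions were not used here, and a base difference between a probe and the R. zephyria transcript can lower its signal in that species.

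The share of probes well above background ranged from 54.2% in larva ZA-5 to 72.8% in larva ZS-1. It was 60.2% ± 3.7 (SD, n = 6) in PA, 61.1% ± 5.8 (n = 5) in ZA and 62.8% ± 6.2 (n = 6) in ZS. The probes were made for R. pomonella, and the share in the 11 R. zephyria larvae was 1.76 percentage points higher than in the 6 R. pomonella larvae, less than the spread between larvae (two-sided exact permutation test over 4704 arrangements, p = 0.486). The differences were 0.825 points for ZA minus PA, 1.71 for ZS minus ZA and 2.54 for ZS minus PA, and all 4 exact tests gave 0.765 after Benjamini-Hochberg adjustment. Single larvae turned the sign of the first (-0.355 without PA-4, -1.34 without ZA-2) and the second (-0.289 without ZS-1, -0.0064 without ZA-5), and the third was 0.536 without ZS-1. The number of arrays and larvae limits the precision of all values below.

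The comparison of ZA with PA asks how the species differ in the same fruit. R. zephyria larvae in apple had far less of several trypsin and storage protein targets and of Jheh1 than R. pomonella larvae in apple, and far more of the trypsin alphaTry. The trypsin-like target thetaTry (contig10762) had a mean log2 signal of 8.18 ± 0.46 (SD, n = 5) in ZA and 16.76 ± 0.55 (n = 6) in PA, a fitted log2 difference of -8.12 ± 0.44 (SE; adjusted p = 2.62e-09). A pair of targets of yellow-d, a member of the yellow gene family, differed by -7.80 ± 0.38 and -6.70 ± 0.21, and Jheh1, an epoxide hydrolase that breaks down juvenile hormone, by -6.79 ± 0.43. In the other direction, 3 targets of the trypsin alphaTry were higher in ZA by 5.76 ± 0.75, 5.13 ± 0.74 and 4.94 ± 0.70, the first with a mean of 16.95 ± 0.52 against 11.36 ± 2.22 (adjusted p = 0.000146). Each of the 5 ZA larvae lay beyond the PA mean in the stated direction for these targets.

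In all, 1605 of the 16561 targets passed the test between ZA and PA, 703 higher and 902 lower in ZA, and 573 of them (156 higher, 417 lower) by at least 2-fold. Targets lower in ZA included LvpD, of the maltase family, at -5.99 ± 0.43 and -5.75 ± 0.33, and 14-3-3zeta, a protein that binds phosphorylated partners, at -5.97 ± 0.28. Targets higher in ZA included Ppn (papilin, of the extracellular matrix) at 2.28 ± 0.39, ninaD (a scavenger receptor for carotenoids) at 1.83 ± 0.37 and 1.64 ± 0.34, Ag5r at 2.36 ± 0.61, PH4alphaNE1 (a prolyl hydroxylase) at 2.65 ± 0.80 and prc (pericardin, of the extracellular matrix) at 2.38 ± 0.62. Pericardin and PH4alphaNE1 were above the PA mean in 4 of the 5 ZA larvae. Tom20, a receptor of mitochondrial protein import, was 1.69 ± 0.27 higher, with 2.32 and 1.07 at its separate probes. Of 20 named targets with 2 probes sharing under 12 bases, 5 had a probe that moved by under 50% of the other on the log2 scale. Among targets below background in one group, Cyp6d4 was at least 16.7-fold and Ssb-c31a, a transcriptional coactivator, at least 14.1-fold brighter in PA than in ZA. In the other direction the largest bound was at least 1.70-fold for takeout (to), a difference that did not pass (adjusted p = 0.334).

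Larval storage proteins, which the fat body makes late in larval life, fell most as a group. Of 36 storage targets 0 rose and 12 fell in ZA (0 and 16 adjusted over the list alone; adjusted p = 6.94e-07, and adjusted p = 0.737 with an estimated correlation). The list also took up 15 hexokinase and hexosaminidase targets through their symbols, and all 12 that fell were among the other 21. Those 12 matched 4 Drosophila genes. Fbp2 (fat body protein 2) differed by -6.65 ± 1.32, -5.82 ± 1.15 and -5.06 ± 0.97, and Lsp2 (larval serum protein 2) by -4.75 ± 1.27, each lower than the PA mean in 4 of the 5 ZA larvae. The exception was larva ZA-2, whose storage list mean was 11.72 on the log2 scale, within the PA range of 11.23 to 12.38. The mean storage difference within the 5 slides was -5.41, -4.04, -3.32, 0.10 and -2.49. Larva ZA-2 was on the slides with -3.32 and 0.10. Slides shared larvae, so values within slides, here and below, are not independent repeats.

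Cytochrome P450s, oxidases of which many act on plant toxins, also fell. Of 143 targets 1 rose and 25 fell (2 and 31 adjusted over the list alone; adjusted p = 0.000441, and adjusted p = 0.737 with an estimated correlation), with within-slide medians of -0.51, -0.39, -0.15, -0.046 and -0.030. The P450 mean of larva ZA-2, 8.71, was within the PA range, while the other 4 ZA larvae lay between 7.95 and 7.99. Cyp6a8 differed by -3.65 ± 0.37 and Cyp6a9 by -2.04 ± 0.25. Cyp6d2, with a mean of 10.35 in PA, was above background in only 35.7% of ZA channels, so no fold is given. Lipases and fat metabolism fell with 0 of 46 targets higher and 3 lower (the same number adjusted over the list alone; adjusted p = 0.000589, and adjusted p = 0.737 with an estimated correlation), including the lipid droplet proteins Lsd-1 at -1.16 ± 0.15 and Lsd-2 at -0.49 ± 0.13, the latter in 4 of the 5 ZA larvae. In amino acid and nitrogen metabolism 0 of 29 targets rose and 5 fell (0 and 7 adjusted over the list alone; adjusted p = 0.00228, and adjusted p = 0.737 with an estimated correlation), among them the aminotransferase Got2 at -3.09 ± 0.44 and -1.48 ± 0.20. This call was lost when arrays were also scaled to the same spread (adjusted p = 0.134) and without larva ZA-2 (adjusted p = 0.0796). Over all alternatives but the estimated correlation the adjusted p of amino acid and nitrogen metabolism ranged from 6.29e-05 to 0.134. Of 85 muscle targets 0 rose and 3 fell (0 and 2 adjusted over the list alone; adjusted p = 0.00228, and adjusted p = 0.791 with an estimated correlation), namely TpnC47D at -0.82 ± 0.23, Mlc1 at -0.65 ± 0.15 and Mhc at -0.65 ± 0.16, the last in 4 of the 5 ZA larvae. The muscle call was lost without larva ZA-1 (adjusted p = 0.0727) and by fry (adjusted p = 0.261), within a range from 2.15e-05 over the alternatives, and lipases and fat metabolism were not called by fry (adjusted p = 0.133).

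Digestive proteases moved both ways, with 3 of 47 targets higher and 9 lower (3 and 11 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.737 with an estimated correlation). The 3 that rose were the alphaTry targets, and those that fell included thetaTry and betaTry at -3.39 ± 0.32. Another thetaTry target, contig24081, had a mean log2 signal of 14.28 ± 1.09 (SD) in the ZA larvae other than ZA-2. It was at 6.63 in ZA-2, 12.57 in PA and 12.82 in ZS, so not every thetaTry target was lower in R. zephyria. This call for digestive proteases was lost without larva ZA-2 (adjusted p = 0.277), without larva PA-4 (adjusted p = 0.0847), with arrays scaled to the same spread (adjusted p = 0.194), with the strict filter on dim probes (adjusted p = 0.327) and with the brightest probe of each target (adjusted p = 0.421), with 0.0027 as the lowest adjusted p of any camera alternative and 0.00129 by fry, which compares with no other targets. Ribosomal proteins rose as a group: 16 of 117 targets were higher and 5 lower (21 and 6 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.737 with an estimated correlation). That call was lost with arrays centred on their medians (adjusted p = 0.288) with the scanner software's processed signals (adjusted p = 0.161) and by fry (adjusted p = 0.194), with 6.76e-05 as the lowest adjusted p of any alternative for ribosomal proteins. The largest changes in it went down: RpS27 at -4.42 ± 0.31, RpS19a at -1.32 ± 0.13 and RpL31 at -0.94 ± 0.10, the last with -1.81 and -0.07 at its separate probes. The ABC transporter list rose (3 of 110 targets higher, 2 lower, 1 and 1 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.826 with an estimated correlation). However, 96 of its members were mitochondrial ribosomal proteins and the gene Wrinkled, which matched by symbol, and without them 0 of 14 targets passed and the direction turned down (adjusted p = 0.618). Of the 5 members that moved, the 3 with the smallest p were mRpL9 at 1.79 ± 0.33, mRpS21 at 1.07 ± 0.28 and mRpL51 at -2.75 ± 0.41, all parts of the mitochondrial ribosome. The ABC transporters were also lost without larva PA-6 (adjusted p = 0.128), without larva ZA-1 (adjusted p = 0.076) and by fry (adjusted p = 0.395), and reached 2.34e-09 without larva ZA-2.

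Other lists were not called between ZA and PA, although single members passed. Glutathione S-transferases had 3 of 19 targets higher and 4 lower (adjusted p = 0.516), with GstE7 at -4.51 ± 0.61 and the GstD1 targets contig20783 and contig24372 at -1.59 ± 0.31 and 2.17 ± 0.47. Carboxylesterases had 2 of 32 higher and 4 lower (adjusted p = 0.398), with alpha-Est7 at -4.14 ± 0.36, and carbohydrate digestion 4 of 25 higher and 5 lower (adjusted p = 0.126). By fry, which compares with no other targets, carbohydrate digestion was called lower (adjusted p = 0.00799). Sugar and polyol metabolism had 4 of 48 higher and 0 lower (adjusted p = 0.962), including Zw (glucose-6-phosphate dehydrogenase) 2.83-fold higher and Pgd (the next oxidative enzyme of the pentose phosphate pathway) at 1.20 ± 0.31, the latter in 4 of the 5 ZA larvae. The ecdysone and juvenile hormone response had 4 of 54 higher and 1 lower (adjusted p = 0.591), with Jheh1 as the lower target. The 4 higher targets matched 1 Drosophila gene. Heat shock proteins had 5 of 51 higher and 6 lower (adjusted p = 0.705), with l(2)efl at -2.14 ± 0.26 and Hsp23 at -1.84 ± 0.36. Mitochondrial respiration had 0 of 53 higher and 3 lower (adjusted p = 0.809), with mt:CoI at -1.51 ± 0.30 and -1.40 ± 0.34, and chemosensory genes 1 of 41 higher and 4 lower (adjusted p = 0.24), with Obp56d at -2.17 ± 0.45. Testis-biased genes had 3 of 18 higher and 0 lower (adjusted p = 0.279), all 3 of them SpdS (spermidine synthase), from 1.39 ± 0.39. The list's median, mean and test differed in sign for peritrophic matrix and chitin (median 0.02, mean 0.13, test down), carboxylesterases (median 0.02, mean -0.33, test down), heat shock proteins (median 0.08, mean -0.04, test up), ovary, yolk and chorion (median 0.05, mean -0.01, test up), neuropeptides and insulin signalling (median 0.04, mean -0.07, test down) and sugar and polyol metabolism (median -0.02, mean 0.04, test up).

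At an unadjusted p under 0.05, 3965 targets differed between ZA and PA. With slide as a block 1045 were called, and over all targets the differences within single slides correlated at 0.541 to 0.908 with the fitted ones, which include the same slides. The count rested on single larvae: it was 3544 without larva ZA-2 (1539 of the 1605 targets shared), 590 without ZA-4, 683 without ZA-5, 858 without ZA-1, 937 without PA-6, 1012 without PA-5 and 1046 without PA-2. With arrays centred on their medians 612 were called, and with the arrays of this pair alone 205.

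**Figure D1:**
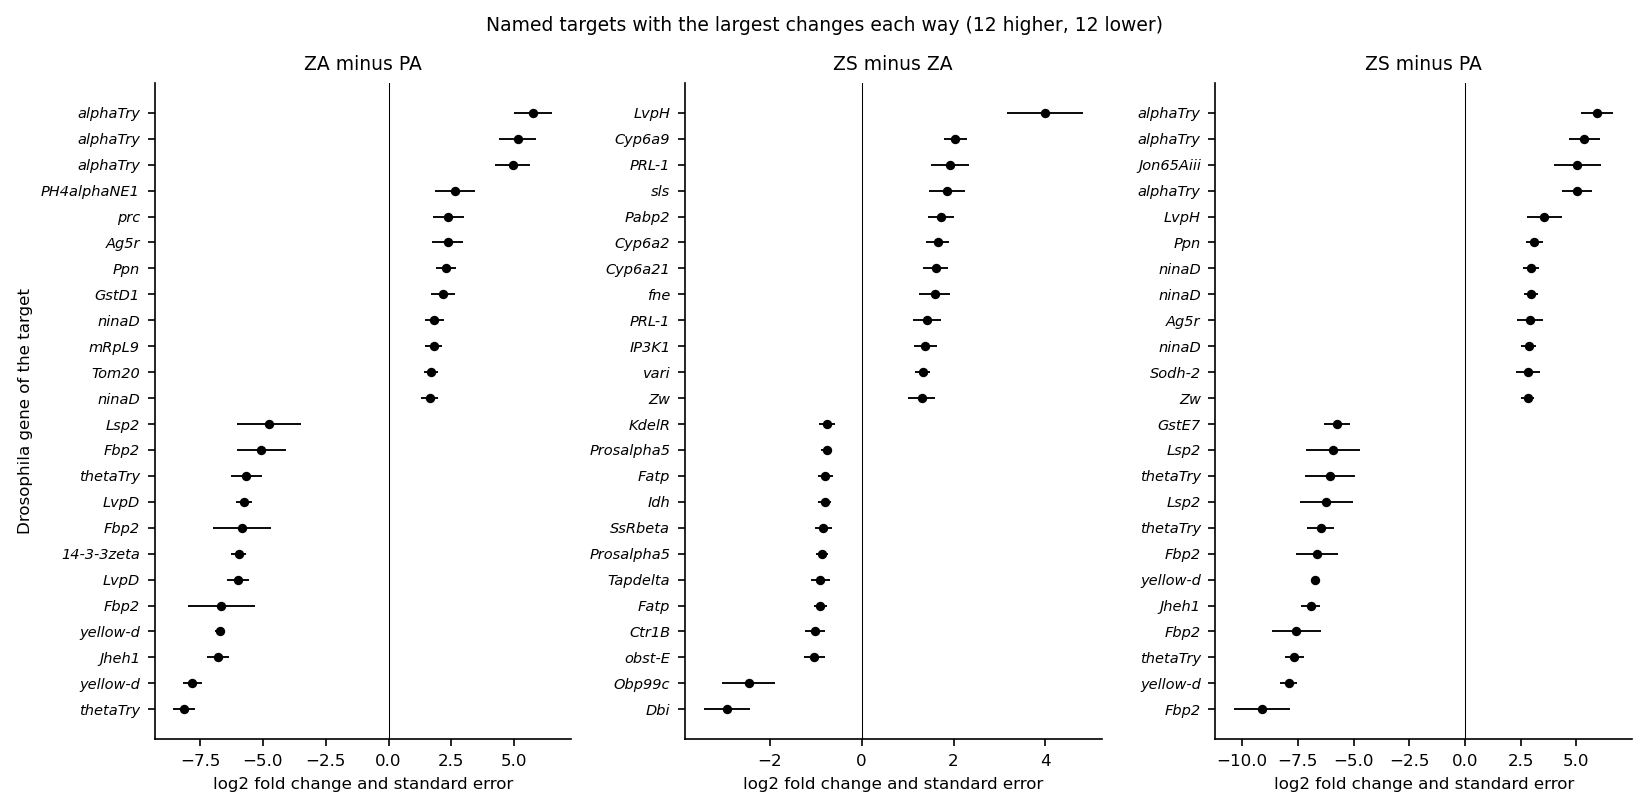
Fitted log2 differences (horizontal axis, log2 scale) with standard errors (bars) for the 12 most higher and 12 most lower named targets that passed the test in each of the 3 comparisons, which the panels show. The values run from -8.12 to 5.76 for ZA minus PA, from -2.93 to 3.99 for ZS minus ZA and from -9.10 to 5.93 for ZS minus PA.

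The comparison of ZS with ZA asks what fruit changes within R. zephyria. Larvae in snowberry, the usual fruit of the species, had more of 4 P450 targets, 3 muscle targets and LvpH, of the maltase family, than larvae of the same species in apple. The P450 list itself was not called. The P450 Cyp6a9 was 2.04 ± 0.25 higher on the log2 scale (adjusted p = 0.000966), at 13.29 ± 0.49 (SD, n = 6) in ZS against 11.25 ± 0.28 (n = 5) in ZA, while PA larvae were at 13.26 ± 0.53. Cyp6a2 was 1.66 ± 0.25 and Cyp6a21 1.61 ± 0.28 higher. LvpH was 3.99 ± 0.82 higher (adjusted p = 0.0231), the largest rise among named targets. Dbi, which binds acyl-CoA, was lower by -2.93 ± 0.50 (adjusted p = 0.00884) and the odorant-binding protein Obp99c by -2.46 ± 0.57. All 6 ZS larvae lay beyond the ZA mean for each of these targets.

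Fewer targets passed here than between the species: 239, of which 174 were higher and 65 lower in ZS, and 93 (73 higher, 20 lower) by at least 2-fold. Higher targets included the phosphatase PRL-1 at 1.92 ± 0.41 and 1.42 ± 0.31, the poly(A)-binding protein Pabp2 at 1.73 ± 0.28, the neuronal RNA-binding protein fne at 1.59 ± 0.34, the kinase IP3K1 at 1.39 ± 0.25, the junction protein vari at 1.33 ± 0.16 and Zw at 1.31 ± 0.30. Lower targets included the copper importer Ctr1B at -1.01 ± 0.22, the fatty acid transporter Fatp at -0.90 ± 0.14 and -0.79 ± 0.16, and the proteasome subunit Prosalpha5 at -0.86 ± 0.14 and -0.76 ± 0.12. They also included 3 proteins of the secretory pathway, Tapdelta at -0.90 ± 0.20, SsRbeta at -0.84 ± 0.18 and KdelR at -0.76 ± 0.17, and Idh at -0.81 ± 0.14. Among targets below background in ZA, 1 of the PGRP-SB1 targets (contig03770) was at least 2.09-fold brighter in ZS. Among those below background in ZS, PGRP-SC2 was at least 2.32-fold brighter in ZA. Neither difference passed (adjusted p = 0.302 and 0.38).

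Muscle rose as a group in ZS, with 3 of 85 targets higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 2.41e-08, and adjusted p = 0.737 with an estimated correlation). The 3 were the giant muscle proteins sls at 1.85 ± 0.39 and bt at 1.26 ± 0.30 and the myosin heavy chain Mhc at 1.28 ± 0.29. The muscle median within the 5 slides was 0.61, 1.05, 0.20, -0.11 and 0.97, and muscle was not called by fry (adjusted p = 0.0792). Storage proteins and genes of DNA replication and cell cycle were lower as lists, with no single member passing: 0 of 36 (also 0 over the list alone; adjusted p = 3.91e-05, and adjusted p = 0.737 with an estimated correlation) and 0 of 94 (also 0 over the list alone; adjusted p = 9.64e-05, and adjusted p = 0.737 with an estimated correlation). Lsp1beta, the storage target with the smallest p, had -2.29 ± 0.88 (adjusted p = 0.191), and the storage mean within the slides was 0.44, -0.32, -2.85, -1.79 and -3.38. Without larva ZA-2 the storage median moved from -1.13 to -0.28, with 2 targets higher and 1 lower (adjusted p = 0.0423, and 0.79 with an estimated correlation). The ABC transporter list was down with 0 of 110 targets passing, and 0 over the list alone (adjusted p = 0.000441, and adjusted p = 0.814 with an estimated correlation). Without its 96 accidental members the direction of ABC transporters turned up (adjusted p = 0.293), and the call was lost without larva ZA-4 (adjusted p = 0.051), without larva ZS-1 (adjusted p = 0.0987) and by fry (adjusted p = 0.475), against 5.04e-11 without larva ZA-2. By fry neither larval storage proteins (adjusted p = 0.157) nor DNA replication and cell cycle (adjusted p = 0.118) were called.

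Antimicrobial peptides and immune recognition were higher in ZS as a list, with 0 of 32 targets passing over all targets and 4 higher and 0 lower adjusted over the list alone (adjusted p = 0.0205, and adjusted p = 0.737 with an estimated correlation). PGRP-LB, a recognition protein for bacterial cell walls, had 1.26 ± 0.33 (adjusted p = 0.0647). The call for antimicrobial peptides and immune recognition was lost without any one of larvae ZA-2, ZA-4, ZS-1, ZS-3 and ZS-5 (adjusted p = 0.1, 0.0707, 0.0698, 0.217 and 0.15), with arrays scaled to the same spread (adjusted p = 0.0957), with processed signals (adjusted p = 0.057) and by fry (adjusted p = 0.192), with 0.00084 as the lowest of any alternative. Neuropeptides and insulin signalling were higher with 0 of 19 passing either way (adjusted p = 0.0332, and adjusted p = 0.737 with an estimated correlation), and ribosomal proteins lower with 0 of 117 (also 0 over the list alone; adjusted p = 0.0302, and adjusted p = 0.814 with an estimated correlation). The call for neuropeptides and insulin signalling was lost under 5 alternatives of processing or test (adjusted p up to 0.237 with the strict filter) and without any one of larvae ZA-1, ZA-2, ZS-1, ZS-5 and ZS-6 (adjusted p = 0.0532, 0.0697, 0.167, 0.0657 and 0.0571), with 0.00223 as the lowest of any alternative. That for ribosomal proteins was lost under 8 such alternatives (adjusted p = 0.114 with slide as a block, up to 0.461 by fry) and without any one of larvae ZA-1, ZA-3, ZA-5, ZS-1, ZS-2 and ZS-4 (adjusted p = 0.0532, 0.0747, 0.266, 0.057, 0.107 and 0.229), with 0.000964 as the lowest.

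**Figure D2:**
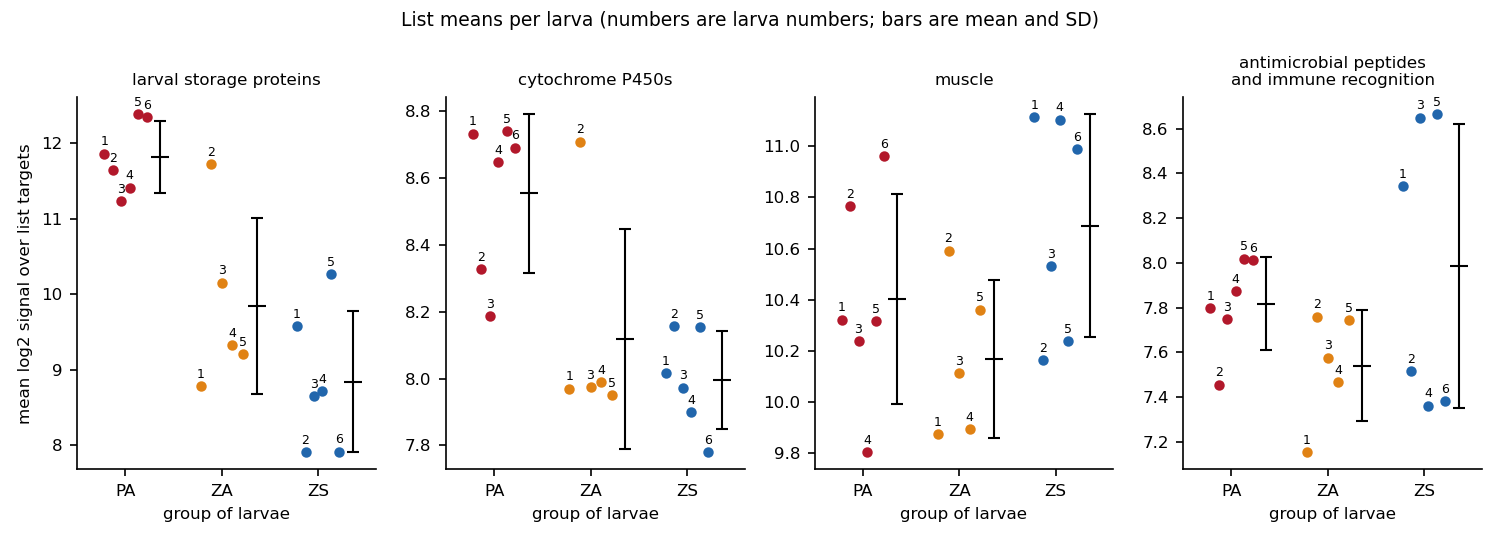
Mean log2 signal (vertical axis) of 4 gene lists in each larva, as points with the larva number, by group (PA n = 6, ZA n = 5, ZS n = 6), with the group mean and standard deviation as a bar. In the storage protein panel larva ZA-2 sits at 11.72 among the PA larvae (11.23 to 12.38), while the other ZA larvae lie between 8.78 and 10.15.

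P450s as a list were not called between fruits (4 of 143 targets higher, 0 lower; 7 and 2 adjusted over the list alone; adjusted p = 0.345). Digestive proteases had 4 of 47 higher and 0 lower (adjusted p = 0.66), among them Jon65Aiii at 1.00 ± 0.18 and Jon65Aiv at 1.15 ± 0.23, and heat shock proteins 3 of 51 higher and 0 lower (adjusted p = 0.549), all of them Droj2 at 0.66 to 0.89. Lipases and fat metabolism had 2 of 46 higher and 0 lower (adjusted p = 0.0633), namely Lsd-1 at 0.84 ± 0.15 and the phospholipase Pld at 1.00 ± 0.19. Amino acid and nitrogen metabolism had 0 higher and 1 lower (adjusted p = 0.516), Gdh (glutamate dehydrogenase) at -0.72 ± 0.14, and antioxidant genes 0 of 38 higher and 1 lower (adjusted p = 0.398), Txl at -0.58 ± 0.13. Chemosensory genes had 1 of 41 higher and 1 lower (adjusted p = 0.904): Csp, a chaperone of synaptic vesicles that matched by symbol, at 0.98 ± 0.16, and Obp99c. Peritrophic matrix and chitin had 0 of 38 higher and 1 lower (adjusted p = 0.398), obst-E at -1.03 ± 0.23. With accidental members left out, lipases and fat metabolism were called lower (adjusted p = 0.0235, and 0.79 with an estimated correlation), against the direction of their 1 passing member, Lsd-1. Carbohydrate digestion was then called higher (1 of 24 targets; adjusted p = 0.0359, and 0.748 with an estimated correlation). Median, mean and test differed in sign for UDP-glycosyltransferases (median -0.08, mean 0.04, test up), cuticle proteins (median 0.03, mean -0.15, test down), haemocyte markers (median 0.02, mean -0.10, test down), carboxylesterases (mean -0.14, test down, with a median above 0) and mitochondrial respiration (median -0.01, mean -0.02, test up).

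At an unadjusted p under 0.05, 2769 targets differed between ZS and ZA. With slide as a block 68 were called, and the differences of all targets within single slides correlated at 0.57 to 0.699 with the fitted ones, which include the same slides. The count depended strongly on single larvae. Without larva ZA-2 it was 2035 (1301 higher, 734 lower), which held all 239. It was 29 without ZA-4, 32 without ZA-3, 67 without ZS-1, 83 without ZS-3, 84 without ZA-1, 109 without ZS-4, 121 without ZS-2, 128 without PA-5, 136 without PA-1, 141 without ZS-5 and 157 without PA-2. With arrays centred on their medians 13 were called, of which 46.2% were higher in ZS against 72.8% of the 239, with processed signals 76 and with the arrays of this pair alone 2.

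Without larva ZA-2 the lists with the most members lower in ZS than in ZA were the ABC transporter list, nearly all mitochondrial ribosomal proteins (0 higher, 24 lower), and DNA replication and cell cycle (1 and 11). Muscle then had 30 targets higher and 1 lower, and peritrophic matrix and chitin 1 higher and 7 lower (adjusted p = 0.00122, and 0.651 with an estimated correlation), which was not called with all larvae. No list was called without this larva when the correlation was estimated. Between ZA and PA, 7 P450 targets rose and 46 fell without this larva, 1 lipase target rose and 26 fell, 2 muscle targets rose and 22 fell, and 19 storage targets fell with 0 higher. Neuropeptides and insulin signalling were then no longer called between the fruits (adjusted p = 0.0697).

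The comparison of ZS with PA sets each species in its own fruit against the other, so species and fruit differ together. The storage protein Fbp2, yellow-d, the trypsin thetaTry and Jheh1 held the largest differences among named targets. The storage protein Fbp2 (contig20370) had a mean log2 signal of 8.41 ± 1.26 (SD, n = 6) in ZS against 17.73 ± 1.08 (n = 6) in PA, a fitted difference of -9.10 ± 1.25 (adjusted p = 0.000132). It was followed by yellow-d at -7.92 ± 0.37, thetaTry at -7.65 ± 0.42, Jheh1 at -6.93 ± 0.41, Lsp2 at -6.22 ± 1.20 and GstE7 at -5.75 ± 0.58. Higher in ZS were alphaTry at 5.93 ± 0.71, Jon65Aiii, another gut serine protease, at 5.04 ± 1.05, LvpH at 3.56 ± 0.78, Ppn at 3.11 ± 0.37, ninaD at 2.96 ± 0.36, Ag5r at 2.94 ± 0.58 and Sodh-2 (sorbitol dehydrogenase) at 2.81 ± 0.53. All 6 ZS larvae lay beyond the PA mean for each of these targets.

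Between ZS and PA 3666 targets passed, 1890 higher and 1776 lower in ZS, and 1020 (388 higher, 632 lower) by at least 2-fold. Of the 902 targets lower in ZA than in PA, 724 were also lower in ZS (96.7 if independent), and of the 703 higher, 481 were also higher (80.2 if independent). Both comparisons share the PA larvae, so chance alone gives a larger overlap than independent sets would. Among targets below background in one group, Ssb-c31a was at least 14.4-fold, PGRP-SC2 (of the peptidoglycan recognition family) at least 4.13-fold and Oat (ornithine aminotransferase) at least 4.09-fold brighter in PA, and LvpD (contig07274) at least 2.18-fold brighter in ZS. Other LvpD targets were lower in ZS, at -5.21 ± 0.32 and -5.39 ± 0.38 in the fit without larva ZA-2.

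**Figure D3:**
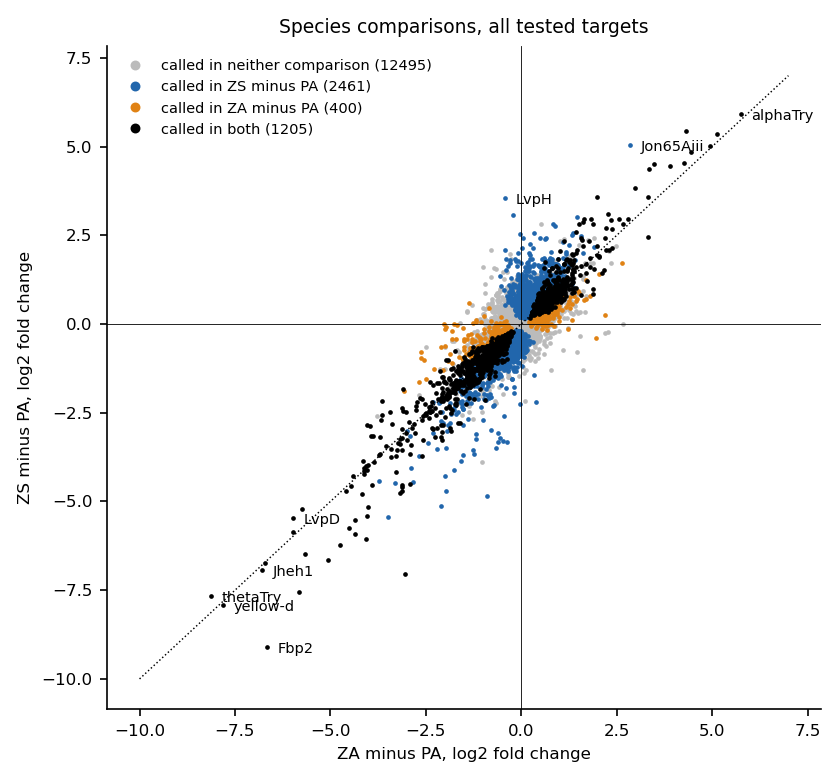
Fitted log2 difference of each of the 16561 targets between ZA and PA (horizontal axis) and between ZS and PA (vertical axis), coloured by the comparison in which it passed the test. Of these, 1205 passed in both, 2461 between ZS and PA alone, 400 between ZA and PA alone and 12495 in neither.

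Storage proteins again fell most, with 1 of 36 targets higher and 25 lower (1 and 26 adjusted over the list alone; adjusted p = 2.84e-11, and adjusted p = 0.737 with an estimated correlation) and within-slide means of -4.97, -4.36, -6.17, -1.69 and -5.87. Of the 21 targets that are storage proteins by name, 19 fell. P450s had 9 of 143 higher and 39 lower (12 and 44 adjusted over the list alone; adjusted p = 0.000143, and adjusted p = 0.737 with an estimated correlation), with within-slide medians of -0.25, -0.44, -0.58, -0.09 and -0.54. Cyp6d4 (contig19969) and Cyp6d2, each with a mean of 10.35 in PA, were above background in only 7.14% and 28.6% of ZS channels, so no fold is given. Lipases and fat metabolism had 1 of 46 higher and 18 lower (the same adjusted over the list alone; adjusted p = 2.29e-05, and adjusted p = 0.737 with an estimated correlation), with sPLA2 at -3.25 ± 0.54, Lsd-2 at -0.69 ± 0.12 and Pld at 1.19 ± 0.18. In amino acid and nitrogen metabolism 0 of 29 rose and 11 fell (the same over the list alone; adjusted p = 0.000589, and adjusted p = 0.737 with an estimated correlation), with Got2 at -1.82 ± 0.42 and -0.99 ± 0.19 and Gdh at -0.62 ± 0.14. Genes of DNA replication and cell cycle had 3 of 94 higher and 18 lower (the same over the list alone; adjusted p = 0.0477, and adjusted p = 0.8 with an estimated correlation), among them the histone His4:CG33909 at -1.82 ± 0.25 and CycB (cyclin B) at -0.83 ± 0.18, with -0.51 and -1.14 at its separate probes. That last list was no longer called under 7 alternatives of processing, for example with arrays centred on their medians (adjusted p = 0.241), nor without any one of larvae PA-1, PA-3, PA-4, ZA-4, ZS-1, ZS-3 and ZS-6 (adjusted p = 0.0659, 0.129, 0.150, 0.0695, 0.144, 0.0594 and 0.0849 for DNA replication and cell cycle), with 0.01 as the lowest and 0.212 by fry. By gene these lists were smaller. The 46 targets of lipases and fat metabolism matched 13 Drosophila genes, and the 18 that fell matched 4. The 25 storage targets that fell matched 8 genes, and the 11 of amino acid and nitrogen metabolism matched 5.

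Among members of lists that were not called, Zw was 2.81 ± 0.29 higher (adjusted p = 6.09e-06), at 13.49 ± 0.41 in ZS, 12.23 ± 0.36 in ZA and 10.65 ± 0.50 in PA, and Pgd 1.84 ± 0.29. Sugar and polyol metabolism, to which both belong, had 10 of 48 targets higher and 3 lower (adjusted p = 0.576). Digestive proteases had 9 of 47 higher and 15 lower (adjusted p = 0.113), glutathione S-transferases 4 of 19 higher and 5 lower (adjusted p = 0.229) and UDP-glycosyltransferases 3 of 16 higher and 0 lower (adjusted p = 0.54), among them Ugt86Di, with a mean of 8.87 in ZS and above background in only 33.3% of PA channels. Carboxylesterases had 5 of 32 higher and 8 lower (adjusted p = 0.315), with alpha-Est7 at -3.86 ± 0.34, Jhedup at -2.85 ± 0.46 and alpha-Est6 at 1.59 ± 0.28. Genes of the ecdysone and juvenile hormone response had 1 of 54 higher and 8 lower (adjusted p = 0.312), with Jhe, an esterase that breaks down juvenile hormone, at -2.06 ± 0.48. Cuticle proteins had 0 of 44 higher and 7 lower (adjusted p = 0.0918), with Lcp4 at -4.47 ± 1.08. Without larva ZA-2 cuticle proteins were called, with 0 higher and 16 lower (adjusted p = 0.0304, and 0.601 with an estimated correlation). Carbohydrate digestion had 9 of 25 higher and 5 lower (adjusted p = 0.769). By fry, which compares with no other targets, digestive proteases (adjusted p = 0.00417) and glutathione S-transferases (adjusted p = 0.0364) were called lower. So were carboxylesterases and the ecdysone and juvenile hormone response (adjusted p = 0.0473 by fry for each).

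Antimicrobial peptides and immune recognition had 5 of 32 higher and 5 lower between ZS and PA (adjusted p = 0.811), with PGRP-LB at 1.39 ± 0.31, heat shock proteins 8 of 51 higher and 9 lower (adjusted p = 0.944), with Hsp23 at -2.50 ± 0.34 and Droj2 at 0.79 ± 0.10, and antioxidant genes 5 of 38 higher and 6 lower (adjusted p = 0.705), with Cat (catalase) at -1.74 ± 0.36. Muscle had 7 of 85 higher and 4 lower (adjusted p = 0.279), ribosomal proteins 15 of 117 higher and 8 lower (adjusted p = 0.315), mitochondrial respiration 6 of 53 higher and 6 lower (adjusted p = 0.718) and chemosensory genes 4 of 41 higher and 8 lower (adjusted p = 0.259), with Obp99c at -3.06 ± 0.55. Peritrophic matrix and chitin had 1 of 38 higher and 7 lower (adjusted p = 0.65), with obst-E at -1.44 ± 0.26. Haemocyte markers had 0 of 15 higher and 2 lower (adjusted p = 0.229), testis-biased genes 3 of 18 higher and 2 lower (adjusted p = 0.217), ovary, yolk and chorion 1 of 14 higher and 3 lower (adjusted p = 0.662) and neuropeptides and insulin signalling 4 of 19 higher and 1 lower (adjusted p = 0.189). Testis-biased genes were called higher by fry (adjusted p = 0.034). However, 8 of the 18 members of that list matched by accident. The other 10 had 2 higher and 1 lower, and camera did not call them (adjusted p = 0.241). The salivary gland list held 1 target, sage at -0.05 ± 0.11 (adjusted p = 0.8). Median, mean and test differed in sign for peritrophic matrix and chitin (mean 0.12, test down), antioxidant genes (median 0.11, mean -0.19, test down), ribosomal proteins (median 0.09, mean -0.01, test up), ovary, yolk and chorion (median 0.08, mean -0.16, test down), sugar and polyol metabolism (median -0.08, mean 0.25, test up) and mitochondrial respiration (median 0.03, mean -0.02, test up).

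At an unadjusted p under 0.05, 5932 targets differed between ZS and PA. With slide as a block 3131 were called, and the differences of all targets within single slides correlated at 0.79 to 0.947 with the fitted ones, which include the same slides. With arrays centred on their medians the median of all targets moved to 0.13 in favour of ZS and 67.8% of 2211 called targets were higher, against 51.6% of the 3666, so the balance of higher and lower targets depended on the scaling. Leaving out any 1 larva gave counts between 2470 and 4976, and without ZA-2, a larva of the group not compared here, 3664 of the 3666 were shared.

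Whether the species difference resembled the response to fruit was asked by setting PA minus ZA against ZS minus ZA. Across the 16561 targets, which are not independent replicates, the correlation of the fitted differences was 0.0411. Because both differences use the same ZA larvae, simulated groups without any effect gave 0.543, so a value above 0 alone says little. The covariance was 0.00841 against 0.0292 simulated. With the ZA larvae split so that each difference used separate larvae, the mean correlation of 6 splits was -0.17 (range -0.304 to -0.0939). Of the targets called in either comparison the correlation was 0.00986, and of the 39 called in both 74.4% had the same sign. By name, 19 targets lower in ZA than in PA were higher in ZS than in ZA (9.48 if independent), as for Cyp6a9, and 10 were higher in ZA than in PA and lower in ZS (2.76 if independent). Larva ZA-2 weighed heavily: the correlation was 0.271 without it and between -0.0177 and 0.136 without any other single larva.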

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

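All tests here were chosen only after the result was seen, except those on other contigs of the same gene, on the second probe of a target and on the storage axis in the species difference. A larva was picked out where its gap to the nearest larva of its group took up an unusually large part of the group's range. Of 81 sets (26 gene lists and the share of probes well above background, in 3 groups) 8 met this, where chance gives about 1 in 20 separate sets, but 7 of the 8 were the same larva and so are not separate. In mean log2 signal, larva ZA-2 lay below the other 4 ZA larvae in cuticle proteins (9.64, the nearest at 11.79), peritrophic matrix and chitin (8.63, the nearest at 10.14) and ABC transporters (8.67, the nearest at 9.47). It lay above them in P450s (8.71, the nearest at 7.99), lipases and fat metabolism (10.00, the nearest at 9.11), haemocyte markers (8.46, the nearest at 7.84) and ovary, yolk and chorion (8.42, the nearest at 7.69). These means include accidental list members. Without them, ZA-2 differed from the other ZA larvae by a mean of -0.006 over 14 ABC transporter targets, so that flag rested on the accidental ones. Over 6 ovary, yolk and chorion targets the mean difference was 0.44. Larva ZS-5 lay below the other ZS larvae in ecdysone and juvenile hormone response (8.66, the nearest at 8.84).

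Across all targets larva ZA-2 departed from its group by a root mean square of 0.948 on the log2 scale, against 0.321 to 0.464 for the other 16 larvae. An R. pomonella larva under a ZA label is argued against. Over 108 targets that separate PA from ZS, the median position of ZA-2 was 0.18, where 0 is the ZS mean and 1 the PA mean. However, 38.9% of these targets were nearer PA, against 8.33% to 16.7% in the other ZA larvae. Because the scale runs only from ZS to PA, it cannot judge another wrong label, such as a ZS larva labelled ZA. Brighter labelling cannot be judged here. Larva ZS-1, bright in the same dye, departed along the same targets by a projection of 0.132, with a correlation of 0.29. Its whole departure was 0.432 against 0.948 in ZA-2, too small to reach the projection set as a match. The comparison also rests on a single larva. Progress through the instar stays open as a candidate explanation, because over 16540 targets outside the storage list the departure correlated at 0.695 with the slope on storage protein level among the 6 PA larvae and at 0.333 among the 6 ZS larvae (one-sided exact p = 0.00694 and 0.0236 over 720 orders of the larvae). The age of each larva was not given, so this may equally reflect another state that varies within groups.

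There were 63 targets at least 8-fold apart in both ZA minus PA and ZS minus PA, the latter of which also differs in fruit, and 84.1% of them (53) were brighter in R. pomonella, whose sequences the probes were made from, so base differences that weaken binding of R. zephyria RNA may account for part of them. For probes 8-fold apart, the partner probe on the same target moved by under 50% as much in 17.9% of 28 (95% interval 6.06% to 36.9%), against 4.88% of 41 (0.596% to 16.5%) for probes 2-fold apart between the fruits, so the intervals overlap and the question stays open. Judged by target, the form of the test fixed earlier, 12.5% of 16 targets (1.55% to 38.3%) had a probe that moved by under 50% of the other. This share was below the share over 50% that base differences predicted and within the 20% allowed otherwise. Its interval reached past that 20%, and the few targets were chosen on the mean of both probes, so base differences are not excluded. Other contigs of the same Drosophila gene moved by a median of 0.377 of the far-apart target (47 targets, quartiles 0.152 and 0.882), which lies between both predictions and mixes paralogs. For probes 2- to 8-fold apart the share was 46.3% of 123 (37.3% to 55.6%), above the 4.88% between fruits, so base differences remain a candidate explanation for part of these smaller differences, beside a true difference between the species. In the counts by probe both probes of a target could enter, so they are not independent and these intervals are too narrow.

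The storage protein level (the mean log2 signal of the 21 storage targets without accidental list members) was 13.5 to 15.3 in PA larvae, 7.92 to 12.1 in ZS larvae, 14.17 in ZA-2 and 9.39 to 11.54 in the other ZA larvae. Probes that cannot bind R. zephyria RNA are argued against as the whole cause, since the level ranged by 4.14 among the 6 ZS larvae. For a shared axis of development, the slope on storage level within groups correlated with PA minus ZS at 0.189 over 16540 targets. This was under 0.2, the bound set beforehand for no such axis, so the result went against it. The value ran from 0.125 to 0.252 when 1 larva was left out, on both sides of that bound, so the axis is not excluded. With the storage level as a covariate in a fit per larva, 578 targets were called between ZA and PA in place of 1464 (400 shared), 595 between ZS and ZA in place of 105 (101 shared) and 1599 between ZS and PA in place of 3553 (891 shared). Storage level and species are largely confounded, so the covariate also takes up part of the species difference. It lowered the precision as well: the median standard error rose from 0.145 to 0.245 for ZS minus PA and from 0.152 to 0.196 for ZA minus PA. The median absolute log2 difference of the targets first called went from 0.644 to 0.569 and from 0.749 to 0.647. The lower counts of these 2 comparisons thus do not measure a share of the species difference due to storage level.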

How the results depend on the processing

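Only the alternatives without accidental list members, without targets of 1 probe per strand, the separate view of larva ZA-2, and the estimated correlation in the latter and without accidental members were chosen after the data were seen. None of the 281 named results reversed, but the balance of higher and lower targets turned in places. ZS minus ZA had 174 higher and 65 lower, and 6 and 7 with median centring. ZS minus PA had 1890 and 1776, and 388 and 632 at 2-fold, 813 and 838 at an adjusted p under 0.01, 1643 and 1665 without PA-3, and 1554 and 1570 without ZA-4. Among called lists, the tests reversed only for ABC transporters without accidental members (adjusted p = 0.618 for ZA minus PA and 0.293 for ZS minus ZA), where 14 of 110 targets were left. Of 210 named results that passed, 124 still passed with median centring, 124 with scaled arrays, 110 with the arrays of the pair alone, 142 at an adjusted p under 0.01, 144 with the replicate block, 173 with processed signals, 176 with slide as a block and 138 without larva ZA-4, the fewest of the larvae left out in turn.

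The counts of targets were 1605 for ZA minus PA, 239 for ZS minus ZA and 3666 for ZS minus PA. At an adjusted p under 0.01 they were 572, 44 and 1651, and with at least a 2-fold change 573, 93 and 1020, both by construction. Median centring gave 612, 13 and 2211, the strict filter on dim probes, which tests fewer targets, 958, 158 and 2269, and ordinary limma, which also calls unchanged targets in simulated data, 4459, 2652 and 6195. For ZA minus PA and ZS minus ZA the arrays of the pair alone, which are fewer, gave 205 and 2, slide as a block 1045 and 68, and the replicate block, although the larva numbers did not pair the larvae, 915 and 19. For ZS minus ZA scaled arrays gave 559, processed signals 76 and separate channels per larva 104. Except where the construction shows it, the cause was not tested.

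Leaving out 1 larva at a time gave 590 (without ZA-4) to 3544 (without ZA-2) for ZA minus PA, 29 (without ZA-4) to 2035 (without ZA-2) for ZS minus ZA and 2470 to 4976 for ZS minus PA. Of the 20 list calls 0 held with an estimated correlation, which also called 0 lists without accidental members and 0 without ZA-2, while leaving out 1 larva gave 16 to 22. By fry 14 lists were called, 1 higher and 13 lower: 12 of the 20 calls were lost and 6 others were gained. The relation of the species difference to the fruit response, 0.0411, was -0.17 with the ZA larvae split, 0.00986 over called targets, and -0.0177 (without ZA-1) to 0.271 (without ZA-2) with 1 larva left out. The larger share of probes well above background in R. zephyria was 1.76 points by the main measure and 0.891 by the less strict one, both within the spread between larvae. Signal over background limits the dim targets, since median raw signals were within a few-fold of the background.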

Other observations

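The genes described first here were picked after their values were seen, and no test was run on them. The tests on regrouped larvae were chosen before their results, but larva ZA-2, which the last of them left out, was picked out from these data. Antimicrobial peptide genes, which fat body and gut switch on after contact with microbes, differed strongly between single ZS larvae. Diptericin B (DptB) had log2 signals of 14.00 in ZS-3, 14.24 in ZS-5 and 9.73 in ZS-1, and 6.82 to 6.87 in the other 3 ZS larvae, against 5.90 to 8.65 in ZA and 6.21 to 7.24 in PA. Cecropin A2 (CecA2) was at 11.93, 11.44 and 10.17 in the same 3 larvae and at 6.76 to 7.06 in the others. The range within ZS was 3.16 for attacin A (AttA) and 4.72 for PGRP-SB1 (7.18 to 11.90), although PGRP-SB1 also reached 11.71 in a PA larva (8.24 to 11.71 in PA, 7.19 to 8.77 in ZA). Over the whole list of antimicrobial peptides and immune recognition the 3 larvae had means of 8.65, 8.66 and 8.34, and the other ZS larvae 7.36 to 7.51.

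Larva ZA-2 departed from its group in transcripts of several kinds. Compared with the other 4 ZA larvae, it had much less of Gld (glucose dehydrogenase, 7.16 against 15.22 ± 0.56, SD, n = 4), of the larval cuticle protein Lcp65Ad (8.18 against 15.49 ± 0.26), of the chitinase Cht5 (7.27 against 14.58 ± 0.56), of the trypsins thetaTry (contig24081, 6.63 against 14.28 ± 1.09) and zetaTry (8.42 against 14.49 ± 0.51) and of TpnC25D (troponin C, 7.29 against 13.29 ± 0.30). It had much more of the fat body protein Fbp1 (17.48 against 7.49 ± 0.87), Fbp2 (17.95 against 8.82 ± 1.20), the phospholipase sPLA2 (14.88 against 6.35 ± 0.64), Fpps (farnesyl pyrophosphate synthase, of the pathway to juvenile hormone, 13.66 against 6.48 ± 0.21), the cuticle protein Cpr49Ac (16.49 against 9.74 ± 0.66) and the P450 Cyp304a1 (13.30 against 7.67 ± 1.60). Among lists, the mean difference of ZA-2 from the other ZA larvae was 3.86 for storage proteins without accidental members, 1.08 for lipases and fat metabolism, -2.28 for cuticle proteins, -1.68 for peritrophic matrix and chitin, -0.98 for UDP-glycosyltransferases, 0.79 for P450s, -0.79 for digestive proteases, 0.68 for haemocyte markers and -0.68 for carboxylesterases, and within 0.64 of 0 for the other lists.

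Targets well above background in at least 50% of the channels of a group and in no channel of the other numbered 99 for ZA and 115 for PA when these were compared, 28 for ZS and 8 for ZA, and 229 for ZS and 123 for PA. Pairs of probes of the same target that shared under 12 bases (1977 pairs) had differences that correlated across targets at 0.732 for ZA minus PA, 0.913 for ZS minus ZA and 0.786 for ZS minus PA. Pairs with 1 probe on each strand (865) correlated at 0.293, 0.332 and 0.282.

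Regrouping the larvae within dyes gave as many targets in under 5% of splits for each count, the share set in advance. This argues against chance as the source of the counts but does not exclude it. Only ZS minus PA exceeded every other split of all larvae. For each comparison of all larvae, 100 of 200 possible splits were drawn. Of 100 splits, the real one included, 2 gave as many targets as ZA minus PA (1605, the highest other 2695), 3 as many as ZS minus ZA (239, the highest other 1410) and 1 as many as ZS minus PA (3666, the highest other 385). Without larva ZA-2, 1 of 100 splits gave as many for ZS minus ZA (2035, the highest other 550). The highest split for ZA minus PA exchanged ZA-2 with PA-3, and that for ZS minus ZA exchanged ZA-2 with ZS-3. These splits called more targets than the real ones, which points to a structure of the samples around larva ZA-2.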
